A study of Danio rerio with 8 samples.

How the data were processed

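Gene expression was measured in blood cells sorted from the kidney of zebrafish at 60 days of age, the organ in which adult fish form their blood. Per the labels, the fish were wild type or a double knockout of the microRNA miR-142-3p, which zebrafish carry in the genes mir142a and mir142b. From each genotype came myelomonocytes (granulocyte and monocyte lineage cells) and whole kidney marrow with the erythrocytes removed. Each of the 4 groups held 2 independent samples, each made from 4 kidneys, so 8 arrays were analysed. Per the labels' protocols, biotin-labelled cRNA was prepared from 200 ng of total RNA for a 1-colour Affymetrix whole-transcript array.

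The deposited table holds 1 log2 value per probe set and array for 75212 probe sets. That the deposited values are on the log2 scale was read from their range. How the authors corrected the background, summarised probes and normalized the arrays is not given in the sources used here, so the values were used as deposited. No value column was left unmapped to a sample. Scan dates and hybridisation batches are not given in the sources used here, so no batch could be tested.

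Probe sets were named through the platform annotation, which is older than current gene names. Of the probe sets, 20806 had 1 gene symbol, 855 had several and 53551 had none here. Of those with 1 symbol, 20323 matched a current zebrafish gene through their Entrez ID in the RefSeq gene table of assembly GRCz12tu, and 1 symbol was updated. That table was used for names and for the order of neighbouring genes only. Probe sets with several symbols were not used. For each of the 19260 symbols the probe set with the highest mean over the 8 arrays was kept. Genes were tested where that mean was at or above 5.52, the 50th percentile of all probe sets, which left 13774 genes and set aside 5486 as dim. Control probe sets are not marked in the table used here, so this level was set over all probe sets. Of the symbols, 1365 had more than 1 probe set. No probe set was paired with mir142a or mir142b, so the loss of the microRNA was not checked on these arrays. Members of families with near-identical copies, such as the MHC genes, may share probes, and their values are uncertain.

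Differences were tested with limma 3.58.1 in R 4.3.3. All 8 arrays entered a single fit with a mean for each group, so the 4 groups shared 1 residual variance per gene with 4 residual degrees of freedom, and eBayes added 4.00 prior degrees of freedom. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the 13774 genes, and a gene was called at an adjusted p under 0.05. The contrasts read from the fit were knockout minus wild type in myelomonocytes, the same in whole kidney marrow, the difference between those differences, and myelomonocytes minus whole kidney marrow in each genotype. Errors of log2 changes are the standard errors of that fit. Errors of levels are SDs over 2 arrays. The number of arrays limits the precision of every comparison.

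The 27 gene lists were fixed before the data were examined, as were the gene tests, most of the alternatives and the rule for naming genes. List tests were planned for the genotype comparisons only, and those of the other contrasts were not planned. The lists hold markers of 11 blood, kidney, endothelial and stromal cell types and genes of 16 pathways, 3 of them defined by a symbol pattern. Some genes belong to several lists, such as psmb10 to the MHC class I and proteasome lists, so the lists are not independent. They were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 27 lists. For 7 list symbols the table's synonyms pointed to an unrelated gene, and these were left out on gene identity after the files were read. Camera with an estimated correlation and fry were run beside it. Fry tests whether a list's genes move, on balance, one way, and does not compare them with other genes. Member counts are given over all genes tested and adjusted over the list alone. Overlaps of calls were tested with one-sided Fisher's exact tests.

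The genes named are up to 12 in each direction with the largest called change in each genotype comparison, with both knockout arrays beyond both wild-type arrays, and up to 8 in each direction in the other comparisons. Symbols that are clone or placeholder names were passed over. In the difference between differences, the condition on single arrays has no meaning and the adjusted p alone was used. Up to 4 members of each list with the smallest p were added, of which the text names called ones. Members of the list of reported miR-142-3p targets that were not called are given as a range, and 1 called member is not reported here.

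The gene tests, camera at the preset correlation and the test of neighbouring calls in gene order were tried on simulated data before use. The other tests were not simulated. The correlation between genes estimated from these arrays ran from -0.035 to 0.48 over the lists, against the preset 0.01. It was 0.347 for erythroid, 0.425 for cell cycle and 0.307 for kidney genes. The trial of camera does not show how often it calls lists falsely at such correlations. In simulated groups with the spread of these arrays, 200 changed genes were planted among the 13774. In the myelomonocyte genotype comparison 68.7% of 1.5-fold, 98.5% of 2-fold and 100% of 4-fold changes were recovered. In whole marrow the shares were 49.3%, 98.5% and 100%. For the difference between differences they were 10.4%, 73.1% and 100%. In each population comparison they were 62.7%, 97.0% and 100%. In the same order, false calls were 11 of 189, 7 of 172 and 4 of 126 calls, and 15 of 188 and 13 of 186 in the population comparisons of wild type and knockout.

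The alternatives tried were no filter on dim genes, a filter at the 75th percentile, the mean of all probe sets of a gene, every probe set above the level whether named or not, and 2 other variance models. Others were quantile normalization, centring each array on its median, array weights, camera with a variance trend, the replicate number as a block, a 2-fold size threshold, only the 4 arrays compared, and leaving out each array in turn. In the last, the remaining sample of the group is assumed to vary like the other groups. A shared pool of fish as a term in the fit was added after seeing the data. A planned test of genes with a miR-142-3p seed match was not run, since no annotated 3′ untranslated regions were used here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.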

Results

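The data set holds expression values for 13774 genes in blood cells from the kidney of adult zebrafish with and without the microRNA miR-142-3p. MicroRNAs are short RNAs that lower the amount or translation of messenger RNAs they pair with, and miR-142-3p is abundant in blood cells. There were 4 groups of 2 independent samples, which were wild-type and knockout myelomonocytes and wild-type and knockout whole kidney marrow. Values are log2 probe set levels from 1 array per sample. Replicate arrays correlated at r = 0.988 to 0.992 across all genes tested, and arrays of different groups at 0.907 to 0.974. Genes are not independent replicates in these correlations. The first principal component held 62.6% of the variance and separated myelomonocytes from whole marrow, and the second held 22.1% and separated knockout from wild type. Neither knocked-out gene had a probe set named here, so the genotype labels were not checked by their own targets.

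The first comparison asked which transcripts differ in myelomonocytes that lack miR-142-3p. In knockout myelomonocytes, 10 of 30 genes of interferon gamma signalling and 8 of 21 of MHC class I antigen processing rose, while 15 of 27 red cell genes and 4 of 37 cell division genes fell. These lists passed camera, but each had an adjusted p = 0.626 with an estimated correlation. ifngr1, a chain of the interferon gamma receptor, rose from 8.06 ± 0.39 to 10.76 ± 0.04 (log2 level, SD, n = 2 per group), a change of 2.69 ± 0.18 (SE). socs1b, an inhibitor of cytokine signalling, rose by 3.06 ± 0.17, from wild-type arrays at 4.53 ± 0.20, below the level of 5.52 used for dim genes. gypc, a red cell membrane protein, fell from 8.67 ± 0.04 to 5.53 ± 0.46, a change of -3.14 ± 0.23. In all, limma called 1703 genes at an adjusted p under 0.05, of which 944 were higher and 759 lower in the knockout, and 377 differed by at least 2-fold. The balance depended on scaling, with 822 higher and 945 lower after centring each array on its median. Besides socs1b, the lower group lay below 5.52, where background can hide part of a change, for and3, cyp46a1.4, gch2, kcnk18, mhc2dgb, plxnb2a.3, mxf, il1rapl1a, stxbp5l, il11b, hspb1 and cd37.

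Among genes that have more than a clone name, the largest rise in myelomonocytes was that of and3, an actinodin otherwise known from fin folds, at 3.90 ± 0.19 (adjusted p = 6.06e-05). It was followed by aqp3a, a water and glycerol channel, at 3.23 ± 0.24 and slc51a, a subunit of a bile acid and steroid exporter, at 3.22 ± 0.38. The potassium channel gene kcnh5a rose by 3.05 ± 0.24, ubald1a by 2.77 ± 0.30 and sh3bp4 by 2.71 ± 0.20. cyp46a1.4 and cyp27a1.1, cytochrome P450 genes of sterol hydroxylation, rose by 2.68 ± 0.36 and 2.61 ± 0.17, the anion transporter gene slco1f1 by 2.56 ± 0.14 and gch2, an enzyme of pteridine synthesis, by 2.50 ± 0.21. The largest fall among them was that of pdxka, a kinase that activates vitamin B6, from 10.02 ± 0.29 to 5.61 ± 0.31 (adjusted p = 0.000122). kcnk18, a potassium channel, changed by -3.53 ± 0.12 and mhc2dgb, an MHC class II chain of a polymorphic family whose value is uncertain, by -3.51 ± 0.47. Changes from -2.44 to -2.07 were measured for plxnb2a.3, mxf, gabbr1a, aldh2.2, il1rapl1a, stxbp5l, bmp1a and brms1la. The call of aldh2.2 was lost without wild-type replicate 1 or 2 (adjusted p = 0.0632 and 0.0628).

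**Figure D1:**
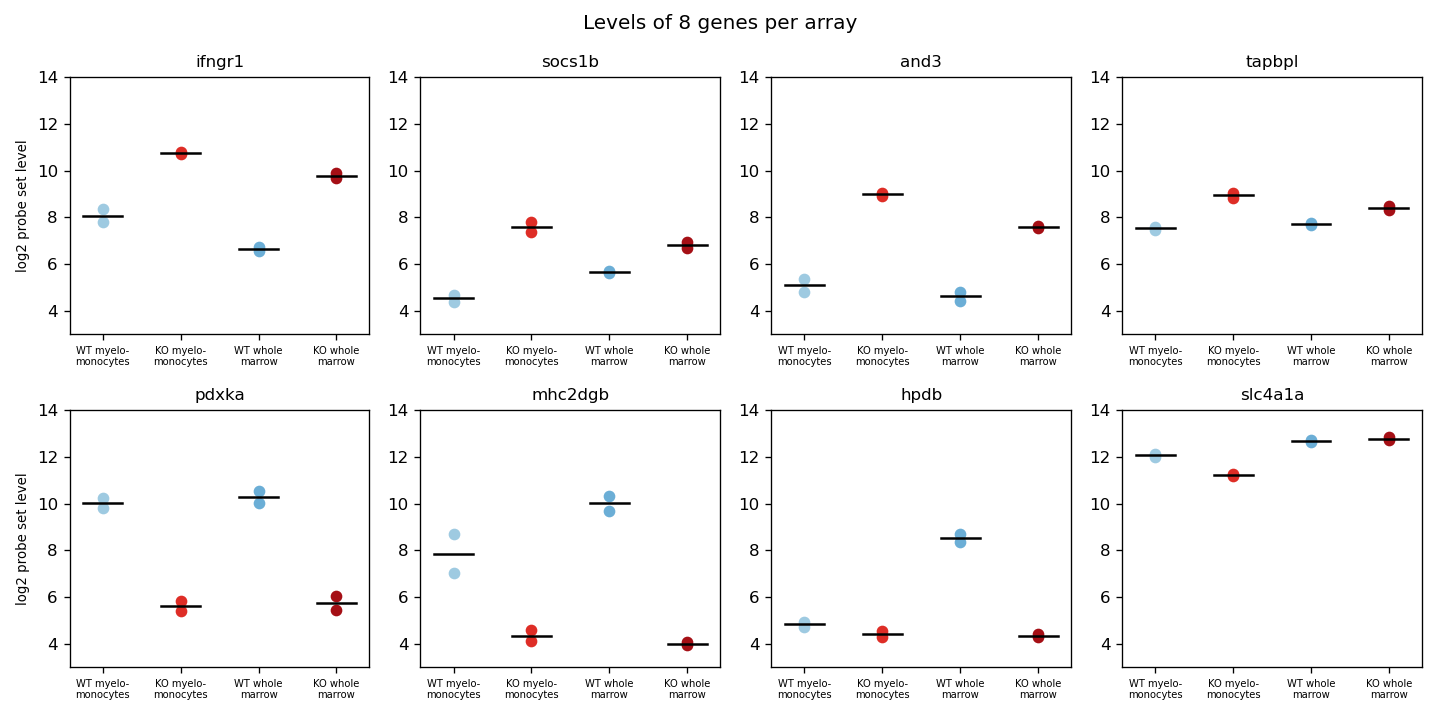
Levels of 8 genes on each of the 8 arrays (log2 probe set level; points are arrays, bars are group means of 2 arrays; WT wild type, KO knockout). ifngr1 lies at 8.06 and 10.76 in wild-type and knockout myelomonocytes and at 6.65 and 9.79 in whole marrow, while slc4a1a is lower in knockout myelomonocytes (11.21 against 12.06 in wild type), with means of 12.68 and 12.78 in wild-type and knockout whole marrow.

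Of 4 immune lists that passed camera in myelomonocytes, 3 were higher in the knockout and 1 lower. Of 30 measured genes of interferon gamma signalling, 10 rose and 20 did not pass (also 10 adjusted over the list alone), with a median of 0.12 and a mean of 0.40 (camera, adjusted p = 0.00548; adjusted p = 0.626 with an estimated correlation). Besides ifngr1 and socs1b these included the interferon response factors irf1b at 1.53 ± 0.18 and irf9 at 1.11 ± 0.11. Of 21 genes of MHC class I antigen processing, 8 rose and 13 did not pass (9 rose adjusted over the list alone), with a median of 0.33 (adjusted p = 9.26e-05; adjusted p = 0.626 with an estimated correlation). The peptide loading genes tap2a and tap1 rose by 1.17 ± 0.13 and 0.70 ± 0.11, tapbpl rose 2.65-fold from 7.54 ± 0.10 to 8.94 ± 0.15, and the proteasome activator psme2 by 0.64 ± 0.10. Among 25 interferon-stimulated antiviral genes, 7 rose and 2 fell (8 and 3 adjusted over the list alone; median 0.28, adjusted p = 0.00394; adjusted p = 0.626 with an estimated correlation). ifit9 and ifit12 rose by 0.89 ± 0.12 and 0.83 ± 0.10, while mxf, an antiviral GTPase, fell. In contrast, 5 of 36 inflammatory cytokine and chemokine genes fell and 31 did not pass (also 5 adjusted over the list alone; median -0.20, adjusted p = 0.00638; adjusted p = 0.626 with an estimated correlation). Among them were acod1, the itaconate-producing enzyme of activated macrophages, at -1.58 ± 0.13, il11b at -1.34 ± 0.29, tnfsf10 at -0.93 ± 0.19 and csf1b at -0.90 ± 0.23. Fry passed the 3 lists of higher genes (adjusted p = 0.0264) and not the inflammatory list (0.133). The calls of il11b, tnfsf10 and csf1b were lost without wild-type replicate 1 or without knockout replicate 2 (adjusted p up to 0.131), that of il11b also without knockout replicate 1 (0.0883), and those of tnfsf10 and csf1b also without wild-type replicate 2 (up to 0.159).

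Erythrocytes are not part of the myelomonocyte sort, but of 27 erythroid genes measured there, 15 fell and 12 did not pass (22 fell adjusted over the list alone), with a median of -0.62 (camera, adjusted p = 2.15e-12; adjusted p = 0.626 with an estimated correlation; fry, adjusted p = 0.0264). slc4a1a, the red cell anion exchanger, changed by -0.85 ± 0.10, sptb, a membrane skeleton spectrin, by -1.12 ± 0.13 and hemgn by -0.71 ± 0.10. The transcription factor gene tal1 changed by -0.97 ± 0.14. Outside the erythroid list, gfi1b of the pan-myeloid list, also active in erythroid precursors, changed by -1.04 ± 0.14, and mllt3 of the stem and progenitor list by -0.96 ± 0.14. Of 37 cell cycle genes, 4 fell and 33 did not pass (14 fell adjusted over the list alone; median -0.42, adjusted p = 7.42e-07; adjusted p = 0.626 with an estimated correlation; fry, adjusted p = 0.143). The 4 were aurkb at -0.74 ± 0.14, chaf1b at -0.71 ± 0.16, birc5a at -0.71 ± 0.19 and top2a at -0.65 ± 0.12, and without either wild-type array none of these kept its call (adjusted p from 0.0529 to 0.160). The call of birc5a was also lost with no filter on dim genes (0.0604), with every probe set (0.0877), after quantile normalization (0.0693) or median centring (0.0512) and with array weights (0.0732), and that of chaf1b with every probe set (0.0515) or only the 4 arrays compared (0.0533). Without knockout replicate 1, top2a, aurkb and birc5a lost theirs (up to 0.175), and without knockout replicate 2, chaf1b and birc5a did (up to 0.0816). Of 27 kidney tubule and podocyte markers, 8 rose and 19 were not called (12 rose adjusted over the list alone; median 0.23, adjusted p = 0.00511; adjusted p = 0.626 with an estimated correlation; fry, adjusted p = 0.184). Examples are slc5a12 at 1.31 ± 0.21, hnf1bb, which rose 2.15-fold, slc13a3 at 1.08 ± 0.26 and wt1b at 0.84 ± 0.20. The kidney list's call was lost without wild-type replicate 1 (adjusted p = 0.0999) or knockout replicate 2 (0.0612), as were those of hnf1bb, slc13a3 and wt1b (up to 0.148). Those of slc13a3 and wt1b were also lost without wild-type replicate 2 (0.113 and 0.0674).

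**Figure D2:**
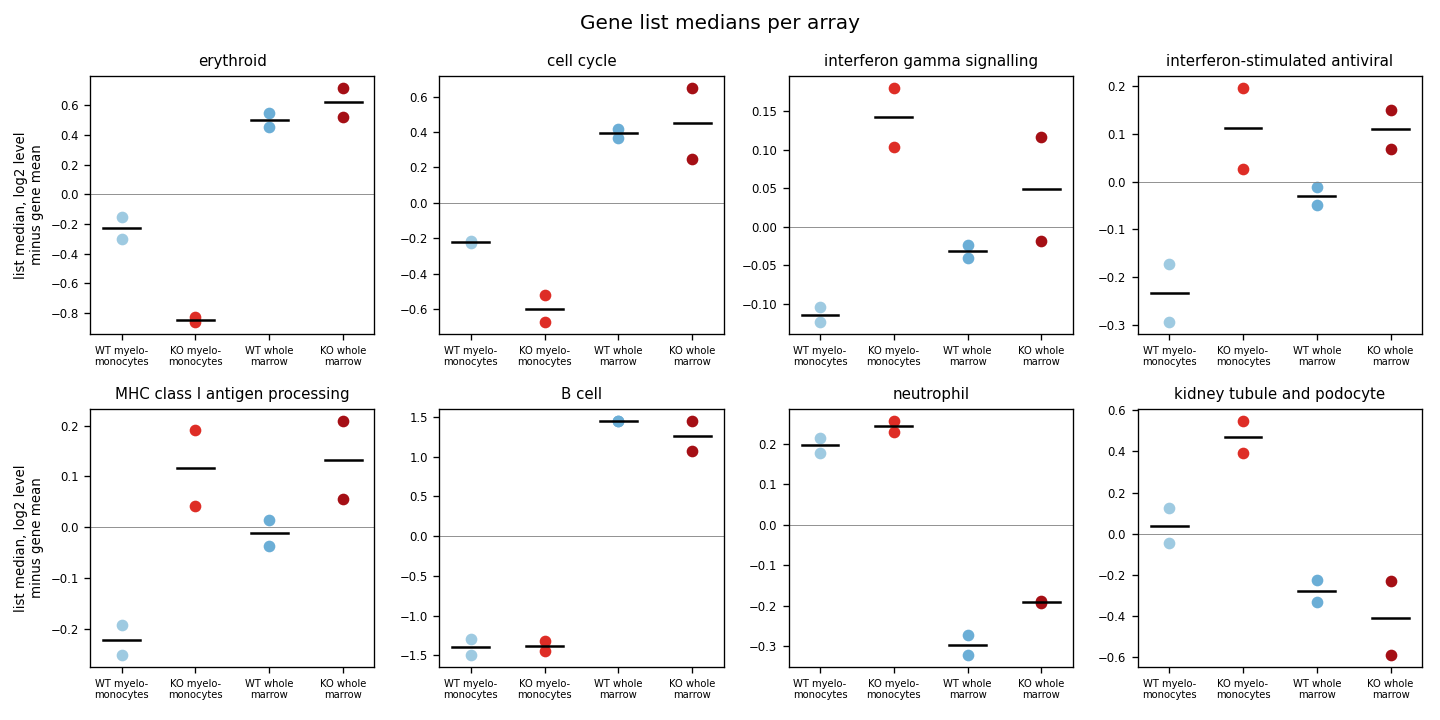
Median of each of 8 gene lists on every array (log2 level after subtracting each gene's mean over the 8 arrays; points are arrays, bars are means of 2 arrays; vertical scales differ between panels). The erythroid list lies at -0.23 in wild-type and -0.85 in knockout myelomonocytes, and at 0.50 and 0.62 in whole marrow.

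The 3 lists of core cellular machinery passed camera in myelomonocytes, each with an adjusted p = 0.626 with an estimated correlation. Of 44 proteasome subunits, 4 rose and 1 fell, with the same numbers adjusted over the list alone (median 0.15). The adjusted p was 0.00548 in camera and 0.0984 in fry. Those that rose included the immunoproteasome subunit psmb10 at 0.67 ± 0.10, which is also a member of the MHC class I list. Of 104 oxidative phosphorylation genes, 6 rose and 1 fell (the same numbers adjusted over the list alone; median 0.09, adjusted p = 0.00738; fry, adjusted p = 0.0984). The gene that fell was uqcrfs1, at -1.10 ± 0.10 by its brightest probe set, but averaging its probe sets gave 0.12 (adjusted p = 0.645). Of 60 ribosomal protein genes, 4 fell and 1 rose (2 and 1 adjusted over the list alone; median -0.08, adjusted p = 0.00851; fry, adjusted p = 0.0424). The proteasome list lost its call without wild-type replicate 2 (adjusted p = 0.0832).

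The other 17 lists did not pass in myelomonocytes. Of 16 neutrophil markers 11 lay above 0 and 5 below, with a median of 0.05 (camera, adjusted p = 0.525), and limma called 0 of them, also 0 adjusted over the list alone, with 3 at an unadjusted p under 0.05. Called members of lists that did not pass went both ways. In the B cell list (median -0.09; 1 of 16 higher and 1 lower, the same adjusted over the list alone) the inhibitory receptor gene cd22 rose by 1.94 ± 0.15 and cd37 changed by -0.70 ± 0.15. In the T and NK cell list (0.12; 3 of 24 higher and 1 lower, 4 and 2 adjusted over the list alone) the kinase gene lck rose by 1.80 ± 0.20, sh2d1ab by 1.13 ± 0.12 and ccr9a changed by -0.55 ± 0.10. In the monocyte and macrophage list (-0.25; 3 of 24 higher and 3 lower, 3 and 5 adjusted over the list alone) grna.2, a granulin, rose by 2.33 ± 0.33 and lgals3bp.1 by 1.95 ± 0.29, while mpeg1.2, a perforin of macrophages, changed by -0.66 ± 0.15. In the immediate early and heat shock list (-0.10; 1 of 39 lower, the same adjusted over the list alone) hspb1 changed by -1.63 ± 0.19. In the p53 and apoptosis list (-0.03; 1 of 37 higher and 2 lower, the same adjusted over the list alone) baxb changed by -0.83 ± 0.12. The list of reported miR-142-3p targets had 24 measured members with a median of 0.00, 12 above and 12 below 0. waslb, an actin regulator, rose by 0.64 ± 0.11 (the 1 call adjusted over the list alone), cdh5, the endothelial cadherin, changed by -0.75 ± 0.20, and the other 22 lay between -0.38 and 0.56. The pan-myeloid (median 0.06, 18 genes), thrombocyte (-0.02, 17 genes), stromal (-0.17, 14 genes) and circadian clock (-0.14, 34 genes) lists had 1 or 2 higher and 1 lower gene each, the same adjusted over the list alone. The stem and progenitor list (-0.05, 19 genes) had 2 higher and 3 lower genes, or 4 and 4 adjusted over the list alone, and the endothelial list (-0.24, 22 genes) had cdh5 as its 1 call, which was not called adjusted over the list alone. The MHC class II list (-0.20, 12 genes) had 1 higher and 2 lower, or 1 and 4, and NADPH oxidase and antimicrobial effectors (0.03, 16 genes) 1 and 1, or 1 and 2. The actin and migration list (-0.04, 40 genes) had 2 higher and 2 lower, or 4 and 2, and glycolysis and hypoxia (-0.00, 41 genes) 3 and 4, or 4 and 5. Adjusted p-values of the 17 ran from 0.0584 for the circadian clock to 0.989 for the targets. Median, mean and test differed in sign for the B cell, thrombocyte, NADPH oxidase, actin, target and glycolysis lists, and the last 4 medians also changed sign with scaling. Of these genes, cd37 lost its call without wild-type replicate 2 or knockout replicate 2 (adjusted p up to 0.134), ccr9a without either wild-type array (up to 0.0706) and mpeg1.2 without wild-type replicate 1 or knockout replicate 2 (up to 0.133). The call of waslb was lost without wild-type replicate 1 (0.0718) and that of cdh5 without any array but knockout replicate 1 (up to 0.219).

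The number of genes called in myelomonocytes depended on both wild-type arrays. Without wild-type replicate 1 or 2, with the remaining sample assumed to vary like the other groups, it was 722 or 719, and within the 4 myelomonocyte arrays alone it was 1108.

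The second comparison asked the same of whole kidney marrow, sampled without its erythrocytes. In knockout marrow ifngr1 was again higher, at 9.79 ± 0.16 against 6.65 ± 0.14 (log2 level, SD, n = 2 per group), a change of 3.14 ± 0.18 (SE). hpdb, a dioxygenase of tyrosine breakdown, fell from 8.52 ± 0.23 to 4.35 ± 0.08, a change of -4.17 ± 0.15, and the lymphocyte genes foxp3a and rag2 changed by -1.50 ± 0.13 and -1.61 ± 0.17. The lists of T and NK cell and of B cell genes that hold them did not pass (camera, adjusted p = 0.878 and 0.251). In all, limma called 1278 genes, 651 higher and 627 lower in the knockout, of which 267 differed by at least 2-fold. The balance was 832 higher and 566 lower after quantile normalization and 640 and 716 after centring on the median. The lower group lay below 5.52 for hpdb, mhc2dgb, plxnb2a.3, ablim1b, asb11, il1rapl1a, stxbp5l, saxo2, cyp46a1.4, and3, cxl34b.11, parp9 and ifit9. After ifngr1, the largest rises of genes with more than a clone name were those of cyp46a1.4 at 3.06 ± 0.36, and3 at 2.97 ± 0.19 and noctb, a nocturnin, at 2.76 ± 0.38, followed by kcnh5a at 2.61 ± 0.24. KANK2 rose by 2.54 ± 0.19, psat1, an enzyme of serine synthesis, by 2.45 ± 0.17, and lgals3bp.1, cxl34b.11, a chemokine gene, alox5b.3, a lipoxygenase, dact1 and cobll1b by 2.30 to 2.36. The largest falls among them were those of mhc2dgb, again uncertain as a member of a polymorphic family, at -6.01 ± 0.47 and pdxka at -4.55 ± 0.26. plxnb2a.3 changed by -2.63 ± 0.31, and ablim1b, asb11, il1rapl1a, aldh2.2, stxbp5l, brms1la, saxo2 and slc12a3, the distal tubule salt transporter, by -2.22 to -1.86. The calls of stxbp5l and slc12a3 were lost without any 1 of the 4 arrays compared (adjusted p up to 0.0795 and 0.192), and that of aldh2.2 without any but knockout replicate 1 (up to 0.142). The number called was 375 or 425 without wild-type replicate 1 or 2 and 515 or 361 without knockout replicate 1 or 2.

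Of the 27 lists, 2 passed camera in whole marrow. Among 44 proteasome subunits 3 rose and 41 did not pass (also 3 adjusted over the list alone; median 0.16, adjusted p = 0.00417; adjusted p = 0.845 with an estimated correlation). They were psmb10 at 0.55 ± 0.10, psmb2 at 0.50 ± 0.10 and psmb4 at 0.41 ± 0.10. Among 34 circadian clock genes 5 fell and 29 did not pass (11 fell and 1 rose adjusted over the list alone; median -0.16, adjusted p = 0.0123; adjusted p = 0.845 with an estimated correlation). They included bhlhe41 at -0.72 ± 0.16, dbpb at -0.57 ± 0.12, per1a at -0.54 ± 0.11 and tefa at -0.44 ± 0.10. Fry passed neither (adjusted p = 0.210 and 0.127). The circadian call was lost without wild-type replicate 2 (adjusted p = 0.0677), and the number of lists passing was 4, 6 and 5 without wild-type replicate 2 and knockout replicates 1 and 2. psmb2, psmb4, per1a, tefa and bhlhe41 each lost their calls without any 1 of the 4 arrays (up to 0.190), psmb10 without any but knockout replicate 2 (up to 0.0990) and dbpb without any but wild-type replicate 1 (up to 0.138).

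Several immune genes changed in whole marrow within lists that did not pass. In interferon gamma signalling 7 of 30 genes rose and 2 fell (11 and 4 adjusted over the list alone; median 0.00, changing sign with scaling, mean 0.24, adjusted p = 0.242). Among them were socs1b at 1.16 ± 0.17, socs1a at 0.96 ± 0.10 and the kinase gene jak1 at -0.48 ± 0.09. ifit9 rose by 0.76 ± 0.12, while parp9 and mxf of the same antiviral list (3 of 25 higher and 2 lower; 8 and 3 adjusted over the list alone) changed by -1.69 ± 0.09 and -1.42 ± 0.29. tapbpl rose by 0.68 ± 0.12 as 1 of 2 called MHC class I genes among 21 (4 rose and 1 fell adjusted over the list alone). Lymphocyte genes that fell were the B cell genes rag2 and cd37 (-1.28 ± 0.15) and the T cell genes foxp3a, cd4-1 (-1.07 ± 0.11) and zap70 (-0.69 ± 0.10), while ccl38.6 rose by 1.15 ± 0.18. In the B cell list 2 of 16 fell (1 rose and 2 fell adjusted over the list alone; median -0.12, adjusted p = 0.251). In the T and NK cell list 3 of 24 rose and 3 fell (5 and 3 adjusted over the list alone; adjusted p = 0.878). acod1 changed by -0.91 ± 0.13 and tnfsf10 fell from 7.08 to 6.08, and il11b rose by 1.86 ± 0.29, as did the immediate early genes jun (1.49 ± 0.29) and fosl1a (1.39 ± 0.24). Of 36 inflammatory genes 3 rose and 3 fell (7 and 4 adjusted over the list alone), and of 39 immediate early and heat shock genes 4 rose (8 rose and 1 fell adjusted over the list alone). Among the reported targets 1 rose and 2 fell. waslb rose by 0.63 ± 0.11 and prom1a changed by -0.76 ± 0.19, and the 21 of 24 that were not called lay between -0.36 and 0.59 (3 rose and 2 fell adjusted over the list alone). The macrophage genes grna.2 and mpeg1.2 changed by 1.77 ± 0.33 and -0.78 ± 0.15, and baxb by -1.18 ± 0.12. uqcrfs1 changed by -1.50 ± 0.10, but by -0.27 (adjusted p = 0.276) when its probe sets were averaged. Erythroid and cell cycle genes had medians of 0.14 and 0.08, and limma called 2 of 27, both lower, and 0 of 37 of them (adjusted over the list alone, 1 rose and 2 fell, and 0), with 3 cell cycle genes at an unadjusted p under 0.05. Adjusted p-values of the 25 lists that did not pass ran from 0.0610 to 0.878, and median, mean and test differed in sign for the pan-myeloid, monocyte, MHC class II and glycolysis lists. Calls lost without any 1 of the 4 arrays were those of jak1, mxf and waslb (adjusted p up to 0.142). Those of prom1a, mpeg1.2 and grna.2 were lost without any but knockout replicate 1 (up to 0.197), of tapbpl without any but knockout replicate 2 (up to 0.0770), and of jun without any but wild-type replicate 2 (up to 0.110). socs1b, tnfsf10 and il11b lost theirs without wild-type or knockout replicate 1 (up to 0.111), fosl1a without either wild-type array (up to 0.0770), and zap70 without either replicate 2 (up to 0.0571). The call of ccl38.6 was lost without wild-type replicate 2 (0.0632), and those of ifit9 and acod1 without knockout replicate 2 (0.0634 and 0.0562).

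The genotype differences in the 2 populations overlapped. Of 944 genes higher in knockout myelomonocytes and 651 higher in knockout marrow, 350 were the same, against 44.6 for independent lists (one-sided Fisher's exact p = 6.48e-251). Of 759 and 627 lower genes, 274 were the same, against 34.6 (one-sided Fisher's exact p = 1.34e-189). ifngr1, and3, kcnh5a, cyp46a1.4, pdxka, plxnb2a.3 and mhc2dgb were among these 624 shared genes. Another 9 genes were called in both with opposite signs, among them anxa1a, il11b and tlr21. Across the 13774 genes, which are not independent replicates, the 2 log2 changes correlated at r = 0.598 (Spearman 0.456). The 2 comparisons take their means from different arrays, but the fit gives each gene the same residual variance in both. A gene with a low variance estimate is therefore more readily called in both, and genes are not independent. The Fisher p-values allow for neither. A shared variance has no sign, and 624 genes kept the same sign against 9 with opposite signs. Fitting only the 4 arrays compared, which gives separate variances, left 466 shared calls. Whole marrow also contains myelomonocytes, and the labels do not say whether both populations came from the same fish. If they did, shared noise would give a covariance of 0.0088, against 0.0879 observed. The shared count was 351 or 361 without wild-type myelomonocyte replicate 1 or 2, 241 or 262 without wild-type marrow replicate 1 or 2, and 282 or 228 without knockout marrow replicate 1 or 2.

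**Figure D3:**
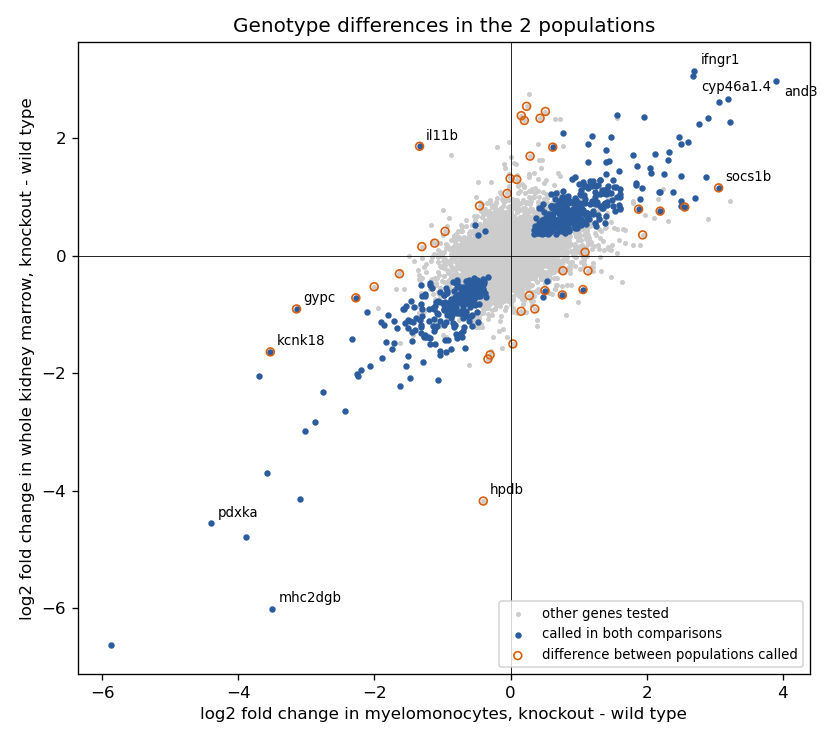
Log2 fold change, knockout minus wild type, of each of 13774 genes in myelomonocytes (horizontal) and whole kidney marrow (vertical). Blue points are the genes called in both comparisons, 624 with the same and 9 with opposite signs, and orange rings the 38 genes whose difference between the populations was called.

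The third comparison tested directly whether the genotype difference depends on the population. limma called 38 genes, with 1924 at an unadjusted p under 0.05. The difference was larger in favour of the knockout in myelomonocytes for 18 genes and in marrow for 20. The count was 2 with every probe set, 23 after quantile normalization and 94 or 112 with the other variance models. Fits that paired same-numbered samples gave more calls, as given below, though no label pairs them. hpdb changed by -4.17 in marrow and differed by 3.77 ± 0.21 (adjusted p = 0.00115), but its myelomonocyte means of 4.83 and 4.42 lay below 5.52 in both genotypes, so a like fall could not have been measured there. socs1b rose more in myelomonocytes than in marrow by 1.90 ± 0.24, and slco1f1 by 1.73 ± 0.20. cd22, tlr21 and anxa1a differed by 1.59 ± 0.21, 1.64 ± 0.18 and 1.43 ± 0.18, the last 2 with opposite signs in the 2 populations. foxp3a, moxd1 and parp9, lower in knockout marrow, differed by 1.53 ± 0.18, 1.42 ± 0.20 and 1.39 ± 0.13. In myelomonocytes foxp3a lay at 5.71 and 5.75 and parp9 at 5.97 and 5.67, near the level of 5.52, so a fall like that in marrow may not have been measurable. In the other direction il11b differed by -3.20 ± 0.41, KANK2 by -2.31 ± 0.27, gypc by -2.24 ± 0.32, cobll1b by -2.10 ± 0.24, psat1 by -1.94 ± 0.23 and cxl34b.11 by -1.91 ± 0.21. kcnk18, gabbr1a, mllt3, sptb and bmf1 differed by -1.89 to -1.31. At least 1 of the 4 groups lay below 5.52 for hpdb, socs1b, parp9, il11b, cxl34b.11 and kcnk18. Apart from hpdb, each of these 20 named genes lost its call with every probe set (adjusted p up to 0.126) and without any 1 of the 4 wild-type arrays (up to 0.189). Without knockout replicate 1 or 2, 11 or 16 of them did for myelomonocytes and 17 or 15 for marrow (up to 0.108). The count was 1, 1, 25 and 11 without wild-type replicate 1 or 2 and knockout replicate 1 or 2 of myelomonocytes, and 1, 2, 7 and 6 without the same arrays of whole marrow.

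As groups, 6 lists passed camera for the difference between the populations, but each had an adjusted p = 0.734 with an estimated correlation, and fry passed none (lowest 0.118, for erythroid genes). Erythroid genes had a median difference of -0.83 (2 of 27 genes called, 21 adjusted over the list alone; camera, adjusted p = 3.52e-19; adjusted p = 0.734 with an estimated correlation). Cell cycle genes had a median difference of -0.44 (adjusted p = 8.48e-10), inflammatory genes of -0.21 (0.00352) and immediate early and heat shock genes of -0.26 (5.56e-05). Kidney tubule and podocyte markers had a median difference of 0.70 (adjusted p = 3.08e-06) and MHC class I genes of 0.19 (0.00127). The inflammatory call was lost without knockout marrow replicate 1 (adjusted p = 0.117). limma called 0 genes in each of the cell cycle, kidney and MHC class I lists, with 11, 10 and 7 at an unadjusted p under 0.05, and 1 MHC class I gene was called adjusted over the list alone. In the inflammatory list 1 of 36 was lower (3 adjusted over the list alone), and in the immediate early list 7 of 39 were when adjusted over the list alone. Of lists that did not pass, median, mean and test differed in sign for neutrophil, stromal and NADPH oxidase genes.

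The population comparisons asked what marks myelomonocytes against whole kidney marrow. In wild type, 11 of 16 neutrophil genes were higher in myelomonocytes, and 13 of 16 B cell, 22 of 24 T and NK cell, 20 of 27 erythroid and 22 of 37 cell cycle genes lower. These lists passed camera, with adjusted p = 0.102 to 0.424 with an estimated correlation. The protease gene mmp9 rose by 1.08 ± 0.11 and the chemokine receptor gene cxcr1 from 11.55 to 12.65, while cd37, a B cell surface protein, fell from 10.53 to 5.83, a change of -4.70 ± 0.15 (SE, n = 2 per group). limma called 4900 genes, 2134 higher and 2766 lower in myelomonocytes, and 860 differed by at least 2-fold. The share of calls that were higher depended on scaling. It was 43.6% as deposited, 58.2% after quantile normalization and 69.7% after centring each array on its median, which moved the all-gene median from 0.00 to 0.17. Again of genes with more than a clone name, the largest rises were those of noctb at 2.87 ± 0.38, tnfsf18 at 2.05 ± 0.26, arg2, an arginase, at 1.86 ± 0.43 and slc7a11, the cystine transporter, at 1.86 ± 0.20, with gpatch4, f2r2.2, prdm1a and nfil3 at 1.62 to 1.79. After cd37, the largest falls were those of the lymphocyte genes ccr7 (-4.58 ± 0.20), il7r (-4.21 ± 0.34) and pax5 (-3.90 ± 0.13), with swap70a, frmpd4, hpdb and rag2 between -3.90 and -3.63. The lower group lay below 5.52 for f2r2.2, frmpd4 and hpdb, which limits their sizes and order. The call of arg2 was lost without wild-type myelomonocyte replicate 2 or marrow replicate 1 (adjusted p = 0.0590 and 0.0780), and the number called was 2950 without wild-type myelomonocyte replicate 2 and 3024 or 3099 without wild-type marrow replicate 1 or 2.

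Of 27 lists, 15 passed in the wild-type population comparison (camera, adjusted p from 1.86e-14 to 0.0447). With an estimated correlation their adjusted p ran from 0.102 to 0.557, so that none passed, while fry passed 19 lists but not the kidney list (0.164). Higher in myelomonocytes were 11 of 16 neutrophil genes (13 adjusted over the list alone; median 0.50, adjusted p = 7.3e-07), such as illr4 at 1.07 ± 0.10 and scpp8 at 0.98 ± 0.11. Of 41 genes of glycolysis and hypoxia 19 were higher and 4 lower (22 and 5 adjusted over the list alone), such as gapdh at 0.79 ± 0.10. Also higher were 14 of 40 actin and migration genes with 4 lower (22 and 5 adjusted over the list alone), such as the cofilin gene cfl1l at 1.06 ± 0.10. So were 12 of 22 endothelial genes (13 adjusted over the list alone), such as cdh5 at 1.11 ± 0.20, erg at 0.81 ± 0.12 and tie1 at 0.75 ± 0.10. Lower were 13 of 16 B cell genes with 2 higher (the same adjusted over the list alone; median -2.98), including ebf1a at -3.42 ± 0.14. So were 22 of 24 T and NK cell genes with 1 higher (23 and 1 adjusted over the list alone; median -1.90), including tcf7 at -3.37 ± 0.14 and cd4-1 at -2.54 ± 0.11. Erythroid genes were lower in 20 of 27 cases (also 20 adjusted over the list alone; median -0.79), such as tal1 at -1.47 ± 0.14, klf1 at -1.25 ± 0.14 and epor at -1.05 ± 0.12. Cell cycle genes were lower in 22 of 37 (26 adjusted over the list alone; median -0.60), such as ccnd1, stmn1a and mcm7 at -1.59 to -1.01, and ribosomal protein genes were lower in 53 of 60 (55 adjusted over the list alone; median -0.47), such as rps18 at -0.75 ± 0.09 and rps12, which fell from 10.34 to 9.34. MHC class II genes, with 7 of 12 lower and 2 higher (the same adjusted over the list alone), included cd74b at -1.25 ± 0.13 and ciita, the class II transactivator, at -2.44 ± 0.17. The macrophage genes csf1rb and irf8 and the immediate early gene egr2b, at -1.87, -2.13 and -2.38, were lower within lists that did not pass. The monocyte and macrophage list had 5 higher and 8 lower of 24 (7 and 9 adjusted over the list alone), and the immediate early list 4 and 10 of 39 (the same adjusted over the list alone). Also higher were 9 of 18 pan-myeloid genes with 4 lower (11 and 4 adjusted over the list alone; median 0.29) and 2 of 27 kidney genes with 1 lower (the same adjusted over the list alone; 0.41). Also lower were 10 of 19 stem and progenitor genes with 3 higher (10 and 4 adjusted over the list alone; -0.38) and 14 of 34 circadian genes with 2 higher (15 and 2 adjusted over the list alone; -0.18). Of 44 proteasome genes 9 were lower and 35 not called (3 lower adjusted over the list alone; -0.17, but 0.01 after centring on the median). Of lists that did not pass, median, mean and test differed in sign for stromal genes and the reported targets. Calls lost without an array were those of the pan-myeloid list without wild-type myelomonocyte replicate 1 or 2 or marrow replicate 1 (up to 0.0834) and the stem and progenitor list without myelomonocyte replicate 2 or marrow replicate 1 (up to 0.0721). That of the kidney list was lost without the same 2 arrays (up to 0.148). The MHC class II call was lost without myelomonocyte replicate 1 or marrow replicate 2 (up to 0.0872) and the proteasome call without myelomonocyte replicate 2 (0.0618), and the pan-myeloid call also after quantile normalization (0.0859) or without the filter on dim genes (0.0761).

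In the knockout, limma called 6076 genes between myelomonocytes and marrow, 2967 higher and 3109 lower, and 1367 differed by at least 2-fold. The share higher was 48.8% as deposited and 65.4% after centring on the median, which moved the all-gene median from 0.03 to 0.17. Of genes with more than a clone name, the largest rises were those of slc12a3 at 2.25 ± 0.45 (SE, n = 2 per group), mfsd2al1 at 2.01 ± 0.23 and slco1f1 at 1.96 ± 0.14, with slc26a6l1, aadacl4, slc47a4, slc51a and sult1st3 at 1.74 to 1.87. The largest falls were those of the lymphocyte genes irf4b (-4.23 ± 0.25), cd37 (-4.12 ± 0.15), il7r (-3.96 ± 0.34) and ccr7 (-3.93 ± 0.20), with frmpd4, pax5, cxcr4a and swap70a between -4.16 and -3.47. The size for cd37 is limited, as it lay below 5.52 in myelomonocytes. Of 27 lists 14 passed camera (adjusted p up to 0.0122), and with an estimated correlation their adjusted p ran from 0.113 to 0.599, so that none passed, while fry passed 17 lists but not the endothelial list (0.0667). Of 27 kidney tubule and podocyte markers 19 were higher in myelomonocytes and 1 lower (21 and 1 adjusted over the list alone; median 1.16, camera adjusted p = 7e-06), such as slc5a12 at 1.45 ± 0.21, slc12a1 at 1.35 ± 0.15 and slc7a9 at 1.14 ± 0.16. Erythroid genes were lower in 24 of 27 cases and cell cycle genes in 35 of 37 (the same adjusted over the list alone; medians -1.57 and -1.02). Neutrophil genes were higher in 13 of 16 cases (14 adjusted over the list alone), such as illr4 at 0.94 ± 0.10 and scpp8 at 0.96 ± 0.11, and the actin gene cfl1l rose by 1.24 ± 0.10. B cell genes were lower in 12 of 16 cases with 2 higher, T and NK cell genes in 21 of 24 with 1 higher and MHC class II genes in 8 of 12 with 2 higher (each the same adjusted over the list alone). Ribosomal protein genes were lower in 53 of 60 cases (57 adjusted over the list alone), immediate early genes in 21 of 39 with 1 higher (22 and 2 adjusted over the list alone) and proteasome genes in 8 of 44 (7 adjusted over the list alone). Actin genes were higher in 24 of 40 cases and glycolysis genes in 22 of 41, each with 5 lower (30 and 25 higher adjusted over the list alone). Pan-myeloid genes were higher in 11 of 18 with 2 lower (13 and 2 adjusted over the list alone) and endothelial genes in 9 of 22 (also 9 adjusted over the list alone). The endothelial call was lost without knockout myelomonocyte replicate 1 (adjusted p = 0.143). Of lists that did not pass, median, mean and test differed in sign for stromal, interferon gamma, antiviral, inflammatory and p53 genes.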

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

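The tests of erythroid, lymphocyte and immune genes below were chosen only after the result was seen, as were the fits with a pool of fish, while the 3 tests on gene order were fixed before their results but after 1 changed gene, hspb1, had been seen beside mir142a. List tests of the difference between the populations were not planned either.

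Genes and gene lists were called in a test of the difference itself, myelomonocytes minus whole marrow, knockout minus wild type on the log2 scale. The 6 lists passed camera, but each had an adjusted p = 0.734 with an estimated correlation and fry passed none, and 19 of the 20 genes named lost their call without some 1 array. Among genes that favoured myelomonocytes, the difference was 3.77 for hpdb, 1.90 for socs1b, 1.73 for slco1f1, 1.64 for tlr21, 1.59 for cd22, 1.53 for foxp3a, 1.43 for anxa1a, 1.42 for moxd1 and 1.39 for parp9. In myelomonocytes hpdb was too dim for a fall to be seen, and foxp3a and parp9 lay near the level of 5.52 in both genotypes. These differences may therefore only reflect low signal. The level of 5.52 is the percentile used as a filter and not a measured background. Among genes that favoured marrow, it was -3.20 for il11b, -2.31 for KANK2, -2.24 for gypc, -2.10 for cobll1b, -1.94 for psat1, -1.91 for cxl34b.11, -1.89 for kcnk18, -1.56 for gabbr1a, -1.38 for mllt3, -1.33 for sptb and -1.31 for bmf1. The list medians differed by -0.83 for erythroid, -0.44 for cell cycle, -0.26 for immediate early and heat shock and -0.21 for inflammatory genes, and by 0.70 for kidney and 0.19 for MHC class I genes.

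The same genes were called in both populations far more often than independent lists would give. The 2 lists are not fully independent, since the fit gives each gene the same residual variance in both comparisons. The knockout fish differ from wild type in the knocked-out loci, and may also differ by sequence variants carried along with them or fixed in the line, which can change a probe's signal. Among 188 tested genes near mir142a and mir142b together, 16 or 8.51% were shared calls, against 4.52% elsewhere, a ratio of 1.88 (one-sided Fisher's exact p = 0.0125). Most of the 16 lay near mir142b, and the loci were not tested apart. The Fisher p-value treats genes as independent. Shared calls clustered in gene order, as given below, so that p-value may be too small. Linked variants remain a candidate explanation for the shared calls near the loci. They cannot account for all shared calls, since wider windows around both loci held 7.32% of them. Shared calls lay next to each other 2.02 times as often as in shuffled order (56 pairs against 27.8; permutation p = 0.000999, the smallest that 1000 shuffles can give), while as many top genes of the wild-type population comparison did so 0.752 times as often, so blocks of sequence difference across the genome stay open beside an effect of the missing microRNA, which was not tested.

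In knockout myelomonocytes 15 of 27 erythroid genes fell, in a list that passed camera but not with an estimated correlation (adjusted p = 0.626). All 6 erythroid genes with the highest level in wild-type marrow (hbaa2, slc4a1a, hbba2, tfr1a, tspo and cahz) lay at least 2 standard errors below 0, 3 of them without a call. Whole marrow carried into the wild-type sort would have brought lymphocytes as well, and the values argue against that, since the erythroid median moved by -0.64 ± 0.21 (SE) relative to the B cell median. Erythroid cells that entered the wild-type sort without lymphocytes would escape this test. The 6 genes belong to a list picked for being lower on these same arrays, with 25 of 27 genes below 0. Their fall was therefore likely beforehand and cannot decide whether fewer erythroid cells were among the knockout sorted cells. That explanation remains open. As a set, erythroid genes were not lower in knockout whole marrow, with a median of 0.14, 20 of 27 above 0 and 2 called, both lower (camera, adjusted p = 0.1665). That marrow was sampled without its erythrocytes, so it cannot settle whether such cells were fewer in the fish or only in the sort.

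In knockout myelomonocytes 8 of 21 MHC class I and 10 of 30 interferon gamma genes rose, and both lists passed camera but not with an estimated correlation (adjusted p = 0.626). More lymphocytes among the knockout sorted cells would raise B cell or T and NK cell genes more, but the MHC class I median rose by 0.32 ± 0.12 (SE) relative to the B cell median and by 0.27 ± 0.06 relative to the T and NK cell median. Single lymphocyte genes did rise, as cd22 by 1.94, lck by 1.80 and sh2d1ab by 1.13, and the T and NK cell list had 3 of 24 genes higher and 1 lower, with a median of 0.12. The kidney list was higher on the same arrays, and the erythroid and cell cycle lists lower (medians 0.23, -0.62 and -0.42). A change in cell types other than lymphocytes was not tested for the immune genes. The higher MHC class I median was not confined to 1 knockout array, since the lower one lay 0.235 above the higher wild-type array (SD of replicate arrays 0.0806). The list was picked for being higher on these same arrays, so this gap was likely beforehand. It cannot decide whether an immune response was stronger in 1 pool of knockout fish, whose medians were 0.19 and 0.04. A response shared by both knockout pools, or an effect of the missing microRNA on ifngr1 and its pathway, stays open. These may be followed up with infection status and 3′ untranslated regions. Sequence differences between the lines, left open above for shared calls, stay open too for ifngr1, which was called in both populations. They were not tested for these lists.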

How the results depend on the processing

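The fits with a pool of fish were chosen only after the result was seen. The other alternatives were planned, save those of the list tests outside the genotype comparisons. Of the called genes followed through the alternatives, 47 of 64 kept direction and call under every alternative but the 2-fold threshold in the myelomonocyte genotype comparison, 29 of 56 in the marrow one, 40 of 41 and 22 of 22 in the population comparisons of wild type and knockout, and 1 of 20, hpdb, which is too dim in myelomonocytes to fall there, in the difference between differences. In the genotype comparisons most losses came from leaving out an array, and 8 and 10 genes were lost under other settings. With every probe set these were chaf1b, birc5a, csf1b, slc13a3, wt1b, cd37, mpeg1.2 and cdh5 in myelomonocytes and slc12a3, aldh2.2, psmb4, tefa, per1a, dbpb, bhlhe41, mxf and prom1a in marrow (adjusted p up to 0.0888). Besides birc5a and chaf1b, csf1b, cdh5, psmb4 and prom1a were also lost with no filter on dim genes and only the 4 arrays compared, mpeg1.2 and tefa with the 4 arrays, slc13a3 and cdh5 with array weights, wt1b after median centring, slc12a3 and prom1a after quantile normalization, slc12a3 with a robust trend, and cdh5, psmb4 and uqcrfs1 (marrow) with the mean of probe sets (up to 0.276). In the difference between differences the 19 others were lost both without some 1 array and with every probe set, in the latter with an adjusted p up to 0.126. Of these, cd22, gypc, sptb, mllt3 and bmf1 were also lost after quantile normalization (up to 0.0647), gypc with the mean of probe sets (0.0682), mllt3 and bmf1 with array weights (up to 0.0518) and bmf1 with no filter on dim genes (0.0552). The genotype calls of anxa1a and tlr21 and the calls of hbaa2 and cahz were not followed. Among these followed genes only uqcrfs1 in myelomonocytes changed sign, at 0.12 with the mean of its probe sets. Some list medians also changed sign with scaling. The cause was not tested.

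Testing every probe set gave 2779 and 2192 calls by genotype in myelomonocytes and marrow, 2 for the difference between differences, and 9939 and 11709 between populations in wild type and knockout, over more features. At least a 2-fold change was seen for 377, 267, 860 and 1367 genes, a subset by construction. Only the 4 arrays compared gave 1108 in myelomonocytes, from fewer samples. For the difference between differences, eBayes with a trend gave 94, with a trend and robust 112, quantile normalization 23 and a pool as a fixed term 254. The cause was not tested.

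Leaving out 1 array, which leaves fewer samples, gave 719 to 1280 genes by genotype in myelomonocytes, 361 to 515 in marrow, 1 to 25 for the difference between differences, 2950 to 3371 and 4088 to 5313 between populations, and 228 to 561 shared by both genotype comparisons. Lists passing camera ranged from 9 to 11 in myelomonocytes and from 2 to 6 in marrow. With an estimated correlation 0 lists passed in either genotype comparison, and fry passed 5 and 0. In marrow, 4 passed with no filter on dim genes and 5 in camera with a variance trend.

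The labels do not say that replicate numbers pair the samples, and deviations of same-numbered samples correlated at 0.405 between the populations of wild type, 0.267 between those of the knockout and at 0.116 or less between other groups. With the replicate block, the counts were 2073 and 1572 by genotype, 77 for the difference between differences, 5344 and 6428 between populations, 772 shared calls and 12 and 3 lists. In wild type the pan-myeloid and the stem and progenitor lists lost their calls under the block (adjusted p = 0.0503 and 0.0544). With a pool as a random term the genotype counts were 1713 and 1285, and as a fixed term the population counts were 5889 and 6890.

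Signal over background limits genes near the level of 5.52, where background can compress changes, such as hpdb in myelomonocytes. Genes with a mean below it were not tested unless the filter was left out. The seed-match result was not run, since no 3′ untranslated regions were used here.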

Other observations

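The values in this part come from no test of their own and were looked at after the tests on gene order.

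The 16 shared calls within 50 tested genes of the knocked-out loci lay 5 near mir142a and 11 near mir142b. In both populations 13 of them were higher and 3 lower in the knockout. Their changes ran from -1.46 to 2.38 in myelomonocytes and from -0.97 to 1.72 in whole marrow on the log2 scale.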
